A study of Arabidopsis thaliana with 6 samples.

How the data were processed

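Gene expression was measured in roots of Arabidopsis thaliana with 6 ATH1 arrays, 3 from jars given 0.125 mM KAuCl4 and 3 from jars without gold, and each array was used as 1 sample. Per the labels' protocols, plants were grown for 14 days, the gold solution was at pH 5.7, and RNA was purified on RNeasy columns and amplified and biotin-labelled with the MessageAmp II kit. The sample labels give an exposure of 24 h while the treatment protocol gives 6 h, and the no gold jars are called untreated in the labels and water-treated in the design text, so the exposure time is not settled here. Per the design text the jars are separate, so the spread between arrays includes differences between jars.

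The deposited table holds log2 values of 22810 probe sets that the authors had centred: every row has a median of 0 over the 6 arrays within 1e-06, and values run from -6.01 to 6.42. The base of the logarithm was read as 2. The summarisation of probes and the scaling between arrays are not given in the sources used here. Column medians lay between -0.0247 (gold replicate 2) and 0.0659 (no gold replicate 1). Centring removes expression levels, so signal over background could not be judged and dim probe sets could not be told from bright ones. The size of a change in a gene near background may be understated or overstated, as the summarisation is not known. The planned filter on the 40% dimmest probe sets, the planned floor and the planned intensity trend all need levels and were not run. The test itself followed the plan, since differences between arrays are untouched by centring of rows.

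After 64 control probe sets were left out, 22746 were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes (default prior), gold minus no gold, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values were used as deposited, without further scaling or filter. Another scaling moved the median change of all probe sets by less than 0.1, from -0.045 to 0.004 (quantile) or -0.007 (array median centring). The probe annotation, from GEO's platform record, listed 14016 probe sets: 13513 carried 1 gene, 503 carried several, and 8730 of those tested were unnamed here. The names cover 13356 genes, of which 11799 have only a locus code; 13436 probe sets matched the TAIR10.1 gene table by gene ID, which served for names alone, and no coordinates are given because the array files name no build. For 146 genes with more than 1 probe set, the planned choice of the brightest could not be made from centred values, and the set without a suffix for shared sequence was taken, then the lowest ID; the 6 genes with 2 or more changed probe sets had 1 direction each.

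Named genes were chosen by a rule fixed before the data were examined: the 12 largest rises and 12 largest falls among named genes that passed the threshold with no overlap of the groups, and up to 4 passing members per list by size of change, or the member with the lowest p where none passed. The 31 gene lists (25 pathways and 6 cell types) were also fixed then. A list member counted as measured only where a probe set was named for that gene alone. Many members had none, so counts and set tests cover only part of most lists. A list with at least 5 measured genes, true of 7, was tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, adjusted over the lists tested. The stems for proteasome subunits and aquaporins were restricted by gene description, to keep out unrelated genes with the same letters. A further 4 protein families were chosen after seeing the data. Errors are standard errors of the limma fit with 3 arrays per group. Control transcripts were compared as the 5' minus the 3' probe set of the same transcript; as rows are centred, this is relative to the median array.

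The procedure was tested on simulated data for gold against no gold with 22746 probe sets: of 100 changed by 1 on the log2 scale 29 were called in the right direction, of 100 changed by 2 there were 79, and 3 unchanged probe sets were called. Camera called a simulated list raised by 1 and did not call an unchanged list. Simulated probe sets varied independently, so this does not show how camera behaves where the genes of a list are correlated. A far smaller share of probe sets was changed than was called in the data, so the call rates need not carry over. The alternatives were array median centring, quantile normalization, array quality weights, the replicate number as a block, each array left out in turn, a minimum of 2-fold, limma treat at 1.5-fold, an ordinary equal-variance test per probe set and the mean of a gene's probe sets; robust empirical Bayes was added later. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.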

Results

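Roots of hydroponically grown Arabidopsis thaliana (Col-0), the small model plant of the mustard family, were profiled on 6 Affymetrix ATH1 arrays, which carry probe sets for most of its protein-coding genes. Jars of plants were the replicates: 3 jars received 0.125 mM KAuCl4, a soluble salt of gold(III), and 3 jars received none. The question addressed was which root transcripts differ in amount after exposure to gold. The deposited values were centred per probe set over the 6 arrays, so differences between arrays were available while expression levels were not, and the number of arrays limits the precision. The logarithm's base was not stated and was read as 2, so every log2 change below rests on that reading. The SD of the centred values within an array ranged from 0.371 for gold replicate 1 to 0.717 for gold replicate 2.

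Quality differed among the arrays, most clearly for no gold replicate 1. On the array of no gold replicate 1, the 5' minus 3' difference of the actin control probe sets was -4.89 on the centred log2 scale, against -1.02 to 0.38 on the other 5 arrays. The difference for GAPDH was -2.55 there and between -0.21 and 0.03 elsewhere. Gold replicate 2 was the next lowest, at -1.02 for actin and -0.21 for GAPDH. Its mean over 4 bacterial control transcripts was -0.73, against -1.16 on no gold replicate 1 and 0.19 to 0.77 on the remaining arrays. Across probe sets, which are not independent replicates, the centred values of no gold replicate 1 correlated with those of the other no gold arrays at 0.48 and 0.46, whereas those 2 correlated at 0.86. Leaving out each array was planned; the choice to give counts without this one beside the main ones was made after seeing the data.

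**Figure D1:**
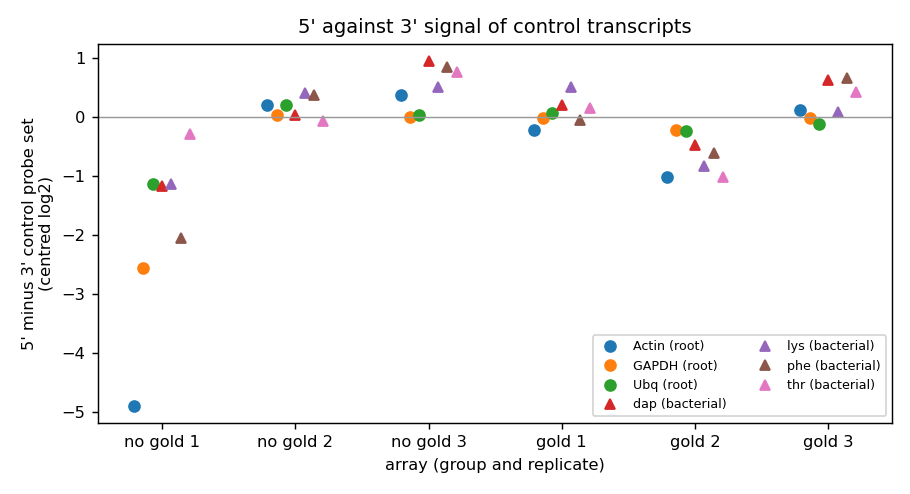
Centred log2 value of the 5' probe set minus that of the 3' probe set, on the y axis, for 3 root transcripts (circles) and 4 bacterial control transcripts (triangles) on each of the 6 arrays, on the x axis, with 1 point per transcript and array. The actin point of no gold replicate 1 sits at -4.89, below all its values on the other arrays.

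With gold, the genes that rose most included a lectin, oxidases, peroxidases and enzymes that transfer or remove sugars. The largest rise among named genes was that of AT3G16530, a lectin of the legume type, at 8.19 ± 0.406 on the log2 scale (SE, n = 3 and 3; limma adjusted p = 2.67e-05). AT1G26380, a FAD-linked oxidase of the berberine bridge enzyme-like family, followed at 7.86 ± 0.803 (limma adjusted p = 0.000484). The class III peroxidases AT1G14550 and AT5G39580 rose by 6.47 ± 0.384 and 6.23 ± 0.261. The glucosyltransferase UGT73B4 rose by 6.06 ± 0.331, the beta-glucosidase BGLU27 by 6.28 ± 0.685 and the cytochrome P450 CYP71B22 by 6.21 ± 0.726. AT4G37290 (6.25 ± 0.506), the small heat shock protein gene AT1G53540 (5.96 ± 0.665), the methyltransferase AT3G54150 (5.80 ± 0.235), the caffeoyl-CoA methyltransferase-like gene CCOAMT (5.68 ± 0.375) and AT3G02840 (5.66 ± 0.67) completed the 12 largest rises. In every one of these 12 genes the 3 gold values lay above the 3 no gold values, which the rule for naming required.

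The largest fall among named genes was that of AT1G73120, at -5.43 ± 0.303 (SE, n = 3 and 3; limma adjusted p = 4.03e-05). AT3G12900, which encodes scopoletin 8-hydroxylase, an enzyme of the iron-mobilising coumarins, fell by 5.21 ± 0.605 (limma adjusted p = 0.000863). UGT72E1, a glucosyltransferase of lignin precursors, fell by 4.26 ± 0.291, and AT3G45710, a transporter of the nitrate and peptide transporter family, fell by 4.53 ± 0.189. AT3G61930 (-4.72), AT5G04730 (-4.70), AT3G19430 (-4.69), AT5G54370 (-4.54), AT4G22460 (-4.45), AT3G18450 (-4.27), AT1G33840 (-4.03) and AT5G19970 (-4.02) were the other members of the 12 largest falls, with limma adjusted p between 1.44e-05 and 0.000312. Changes of this size were more often rises: 164 probe sets rose and 30 fell by at least 4 on the log2 scale.

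**Figure D2:**
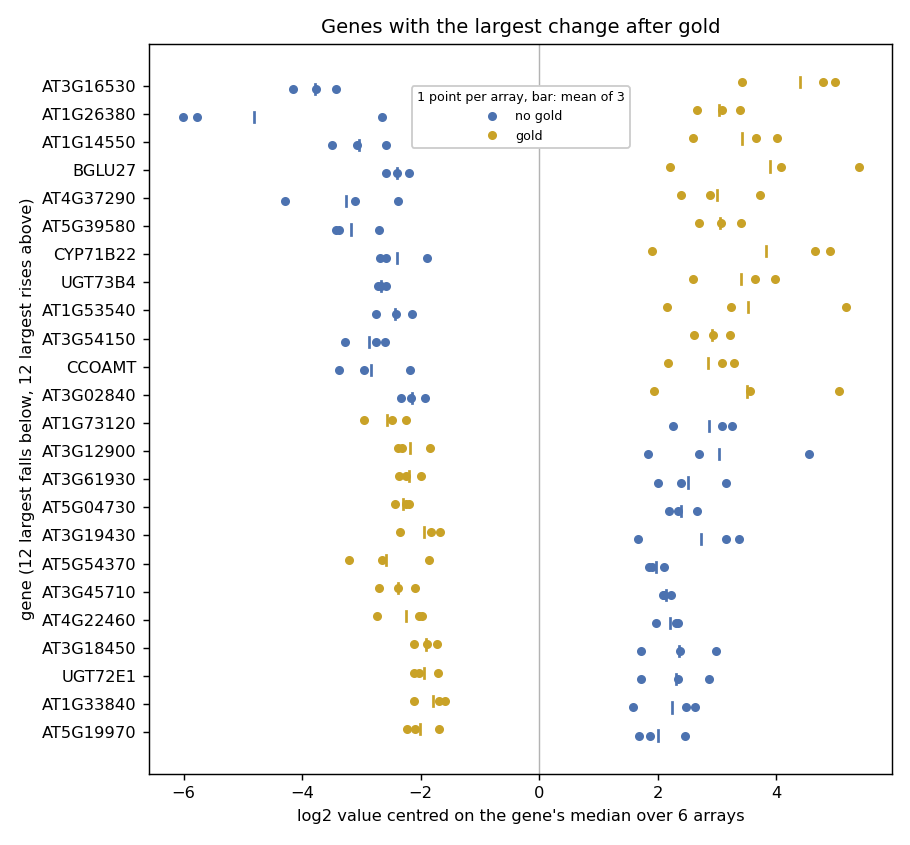
Centred log2 values, on the x axis, of the 12 named genes with the largest rise and the 12 with the largest fall, on the y axis; each point is 1 array of the gold or no gold group and each vertical bar is the mean of 3. The gold points lie above the no gold points for the rises and below them for the falls, from AT3G16530 with a change of 8.19 to AT1G73120 with a change of -5.43.

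In all, 4601 of 22746 probe sets (20.2%) changed at an adjusted p below 0.05, with 2121 higher and 2480 lower with gold. Among the 13356 named genes, 1070 rose and 1300 fell. A change of at least 2-fold was seen in 1590 higher and 1456 lower probe sets. Among named genes alone, with 1 probe set each, the counts were 787 and 741. Of the 4601 changed probe sets, 2213 had no single named gene. The groups did not overlap in 37.2% of probe sets, where chance gives 10% for 3 against 3. Without the array of no gold replicate 1, 2151 probe sets were higher and 2717 lower, and 4054 of the 4601 (88.1%) kept their call and direction. The counts moved by more than 1.5 times when certain other arrays were left out: to 1262 higher and 1258 lower without gold replicate 3, to 1565 lower without no gold replicate 2 and to 1625 lower without gold replicate 2. With 3 jars per group the smallest two-sided exact permutation p for a single gene is 0.1, so the calls rest on limma's pooling of the spread over probe sets. Among genes named in the gene list accounts, an ordinary test without that pooling ended the calls of ATGSTF13, APS3, GR1, SIR, AT1G04770, BGLU42, ZIP9, MTP11, LEA4-5, WRKY53, EXPA18, EXPA7, AT1G30870, AUR2 and TOPII (adjusted values from 0.0502 to 0.130).

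Tau-class glutathione transferases, enzymes that couple glutathione to reactive or foreign compounds, split in both directions. Of 11 measured members, 3 rose, 4 fell and 4 did not pass the test. Other members, GSTU19 and GSTU24 among them, had no probe set named for 1 gene and are not covered. GSTU25 rose by 5.63 ± 0.223 and GSTU22 by 2.85 ± 0.257, whereas GSTU20 fell by 3.45 ± 0.244 and GSTU28 fell by 2.53 ± 0.249 (SE, n = 3 and 3). The list did not shift as a whole against other genes (median -0.13; mean 0.01; camera adjusted p = 0.806), while the fry test for change in either direction gave an adjusted p of 0.00019; that test passed for all 7 lists tested (0.00019 to 0.00343). The median and mean of the list differed in sign. Of 3 other glutathione transferases, ATGSTF13 fell by 1.86 ± 0.277 and 2 did not pass. Without the array of no gold replicate 1, whose control transcripts had low 5' signal, the tau-class counts were again 3 higher and 4 lower.

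Measured genes of the response to electrophiles and foreign compounds were mostly higher: 4 of 6 measured members rose, 1 fell and 1 did not pass. Most members, CYP81D11, OPR1 and ABCG40 among them, had no probe set named for 1 gene and are not covered. UGT73B4 rose by 6.06, the related UGT73B5 by 4.12 ± 0.415, the alkenal reductase gene AER by 4.02 ± 0.486 and AT2G04070, an efflux carrier of the MATE family, by 1.21. UGT72E1, which conjugates lignin precursors, fell by 4.26. By locus code UGT73B4 and UGT73B5 are neighbours that may share probe signal, which was not examined here. The list's median change was 2.61, with camera adjusted p = 0.0109 at the preset correlation and adjusted p = 0.467 with an estimated correlation. Without the low-5' array of no gold replicate 1 the counts stayed at 4 and 1, and the camera adjusted p was 0.0635.

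Sulfate assimilation and glutathione metabolism had 3 of 5 measured members higher and none lower. The ATP sulfurylase APS3 rose by 2.47 ± 0.536, the glutathione reductase GR1 by 1.46 ± 0.226 and the sulfite reductase SIR by 1.08 ± 0.262. The list did not pass as a set (median 1.08; camera adjusted p = 0.0775; adjusted p = 0.467 with an estimated correlation). Without the low-5' array of no gold replicate 1, 3 members were higher and 1 lower. Both measured markers of sulfur deficiency rose: BGLU28, a beta-glucosidase, by 4.92 ± 0.344 and AT1G04770 by 0.58 ± 0.166. Single arrays decided 3 of these calls: AT1G04770 lost its call without any 1 of the 6 arrays (limma adjusted p up to 0.143) and with the replicate block (0.0782), SIR without no gold replicate 2, gold replicate 2 or gold replicate 3 (up to 0.104), and APS3 without gold replicate 3 (0.0688).

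Among metal-related genes, those linked to iron deficiency included falls and no rise that passed. Of 5 measured members, AT3G12900 fell by 5.21 and BGLU42, a beta-glucosidase that releases coumarins from their glucosides, fell by 1.87 ± 0.329. The other 3 did not pass and went both ways: BHLH101 was at -0.70, PYE at 0.30 and AT3G13610, the F6'H1 gene of this list, at 0.55. IRT1, FRO2 and FIT1 of this list were among members with no probe set named for 1 gene. The set test gave camera adjusted p = 0.224 and adjusted p = 0.538 with an estimated correlation, while 3 members were lower adjusted over the list alone. MT1C, a metallothionein, fell by 1.81 ± 0.236 as the sole measured member of the chelation list. The zinc transporter gene ZIP9 fell by 1.14 ± 0.217 and the manganese transporter gene MTP11 rose by 0.99 ± 0.216, with 1 further member of that list not passing; MTP11 lost its call without gold replicate 2 or gold replicate 3 (limma adjusted p up to 0.0729). The copper chaperone gene CCS was at 0.70 ± 0.27 (limma adjusted p = 0.119), a value that passed when adjusted over the list alone, which held 1 gene, and under quantile normalization (limma adjusted p = 0.0479). Without the low-5' array of no gold replicate 1 its change was 0.38 (limma adjusted p = 0.113).

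Stress regulators included several rises. In the list for reactive oxygen and mitochondrial stress, 2 of 5 members rose (3 without the low-5' array of no gold replicate 1), the zinc finger gene STZ by 3.31 ± 0.359 and NDB2, an alternative NADH dehydrogenase of mitochondria, by 2.70 ± 0.301. Of 7 WRKY transcription factor genes, WRKY6 rose by 3.04 ± 0.334 and WRKY53 by 1.64 ± 0.28, and 5 did not pass. WRKY53 was also the only measured member of the salicylate and defence list. Neither list passed as a set (camera adjusted p = 0.0775 and 0.116; both adjusted p = 0.467 with an estimated correlation). BZIP60, a transcription factor of the endoplasmic reticulum stress response, rose by 1.49 ± 0.17, while the other 2 members of its list did not pass. Of 4 genes of the abscisic acid and water deficit response, LEA4-5 rose by 1.88 ± 0.291 and the dehydrin gene LTI30 rose as well (limma adjusted p = 0.00439). None of the 3 measured members of the heat shock list passed over all genes (AT5G48570 at 2.14 ± 0.641, limma adjusted p = 0.0522), and all 3 were higher adjusted over the list alone, as they were over all genes under quantile normalization. AT5G48570 also passed with the replicate block (0.0361) and without gold replicate 1 (0.00491). AT1G53540, a small heat shock protein gene outside that list, was among the 12 largest rises at 5.96.

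Cell wall loosening genes, expansins and xyloglucan-modifying XTH enzymes, went both ways, with 5 of 29 higher, 9 lower and 15 not passing. XTH29 rose by 3.32 ± 0.378, while XTH26 (-3.03 ± 0.359), XTH21 (-2.81 ± 0.307) and EXPA18 (-2.36 ± 0.383) fell. The set test gave camera adjusted p = 0.386 and adjusted p = 0.467 with an estimated correlation, and adjusted over the list alone 5 were higher and 10 lower. Without the low-5' array of no gold replicate 1, 4 were higher and 12 lower. All 3 measured cell cycle genes fell, the Aurora kinase genes AUR2 (-1.47) and AUR1 (-0.91) and the topoisomerase gene TOPII (-1.45), and all 3 fell without that array too. With limma treat at 1.5-fold all 3 lost their call (adjusted p = 0.0751 for AUR2, 0.327 for AUR1 and 0.0541 for TOPII), and with the ordinary test AUR2 (0.0827) and TOPII (0.0649) did. Single measured members of the lists for jasmonate (JMT, -0.01), ethylene (PDF1.2, 0.09), nitrate uptake (NRT2.5, 0.23), flavonoid synthesis (DFR, -0.10) and the proteasome (RPN12a, 0.30) did not pass the test.

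Markers of cell types were thinly covered. The 3 measured root hair genes fell: the peroxidase AT1G30870 at -2.53 ± 0.361 and the expansins EXPA18 at -2.36 ± 0.383 and EXPA7 at -2.34 ± 0.354 (SE, n = 3 and 3), with both expansins also counted in the cell wall list and AT1G30870 a class III peroxidase. They fell without the array of no gold replicate 1 as well, but all 3 lost their call with the ordinary equal-variance test per probe set, at adjusted values of 0.0567 (AT1G30870), 0.0728 (EXPA18) and 0.0628 (EXPA7). RCA, the activase of Rubisco and a marker of shoot tissue, fell by 1.49 ± 0.226, and PRK, a photosynthesis gene of the same list, was at -1.48 without passing over all genes (limma adjusted p = 0.0737). The phloem gene SWEET11 was at -0.81 ± 0.27 and the root cap gene CR4 at -0.54 ± 0.172, and these 2 and PRK were lower when adjusted over the list alone. The phloem and root cap lists held 1 measured gene each, so for SWEET11 and CR4 that step adjusted nothing. SWEET11 also passed over all genes without no gold replicate 3 (limma adjusted p = 0.0381) or gold replicate 2 (0.0423). In the other lists fixed before the data were examined, where no separate count is given, the counts adjusted over the list alone equalled those over all genes. Markers of endodermis and of xylem, together with phosphate response genes, aquaporins and ABC transporters, were not analysed here because no member had a probe set named for 1 gene.

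**Figure D3:**
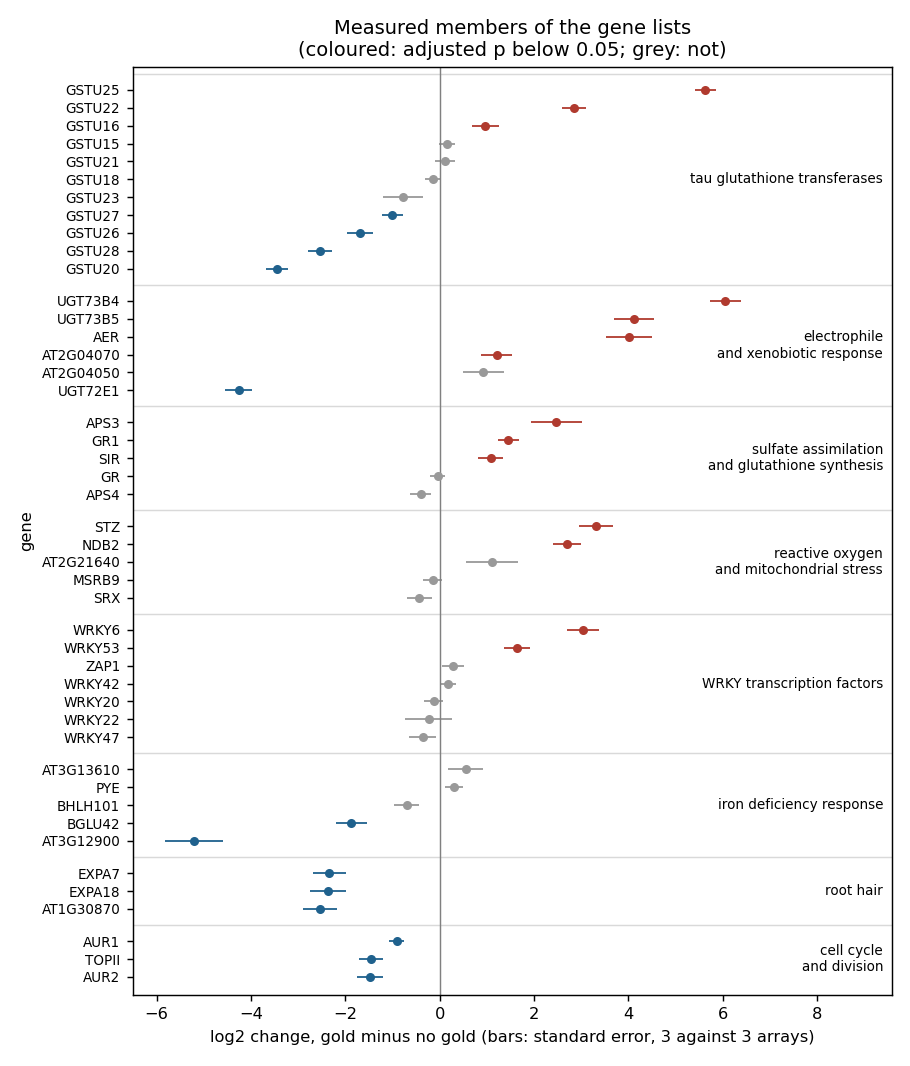
Log2 change with gold, on the x axis, of the measured members of 8 gene lists, on the y axis; points are limma estimates from 3 against 3 arrays, bars are standard errors, and colour marks an adjusted p below 0.05 (red higher, blue lower, grey not). Tau-class glutathione transferases spread from GSTU20 at -3.45 to GSTU25 at 5.63, whereas the 3 root hair and 3 cell cycle genes all lie below 0.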

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

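Robust empirical Bayes was chosen after the data were seen; the other settings were planned. Among 79 genes chosen by the rule or by the added families, no called value reversed; 17 lost their call with the ordinary test (AT2G21100 and AT1G50060 of the added families among them), 9 with treat (APS3, SIR, AT1G04770, ZIP9, MTP11, LTI30, AUR1, AUR2 and TOPII) and up to 4 with 1 array left out. Array quality weights gave 5442 higher and 6366 lower probe sets (2970 and 3541 named genes), with weights from 0.155 for no gold replicate 1 to 15.8 for gold replicate 3, whose estimation did not converge. Limma treat at 1.5-fold gave 968 and 757 (477 and 381) and the ordinary test per probe set, which does not pool the spread, 922 and 1015 (463 and 513). A minimum of 2-fold gave 1456 lower probe sets (741 named genes). Leaving out each array in turn gave 1262 to 2432 higher and 1258 to 2717 lower probe sets, and 624 to 1215 higher and 630 to 1397 lower named genes, the lowest without gold replicate 3; fewer arrays were tested, and the cause of the differences among arrays was not tested. With the replicate number as a block, 3949 probe sets changed, 3739 of them shared with the 4601. Same-numbered arrays deviated from their group means with correlations of -0.11, -0.25 and 0.28. The value for the replicate 3 arrays was the highest of all pairs, but not every array correlated best with its own number. Deviations within a group of 3 depend on each other, so these few values cannot decide whether the numbers pair the jars. For the lists, the electrophile shift had adjusted p = 0.467 with an estimated correlation and 0.0021 to 0.0635 with arrays left out. The sulfate list passed with the replicate block (0.0415) and ranged from 0.0309 to 0.215 with arrays left out, the reactive oxygen list from 0.0309 to 0.125 (fry 0.0275) and the WRKY list from 0.0461 to 0.334; cell wall loosening passed with fry (0.0275), which asks another question. The cause was not tested for these. Array median centring, quantile normalization and robust empirical Bayes kept each count within 1.5 times, and the first 2, run on the lists too, kept each list on its side of 0.05. The dim filter, the floor and the intensity trend were not run, since the deposited values hold no levels, and signal over background limits were unknown.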

Other observations

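The comparisons in this part were chosen after the results were seen. The limma calls they use, and the counts under other settings, come from tests that were planned. 4 protein families with 2 or more members among the 120 named genes with the largest called changes were examined as groups. Class III peroxidases, secreted enzymes that act on hydrogen peroxide and phenolics, changed more often than other named genes and in both directions: 14 of 55 rose and 15 fell (52.7% changed, against 17.7% of all named genes; Fisher's exact test, adjusted p = 1.62e-08 over 4 families). One of the falls, AT1G30870 at -2.53, is also a root hair marker, and all 3 measured root hair markers fell. The family's median change was -0.24 and its mean 0.25, with camera adjusted p = 0.383. AT5G19880 rose by 5.55 ± 0.289 and AT5G06730 by 4.90 ± 0.188 (SE, n = 3 and 3), beside AT1G14550 and AT5G39580. After those 120 genes, which had prompted the choice, were left out, 22 of 48 peroxidases had changed against 16.9% of other genes (adjusted p = 1.23e-05). Without no gold replicate 1, whose array had low 5' signal, 15 rose and 15 fell. Fisher's exact test counts genes as independent, here and for the other families. All were read on the same 6 arrays, and members of a family can change together, so these p-values may be too small. Genes not expressed in roots could not be left out of the comparison, since the values hold no levels. Proteins of the CAP family, secreted proteins related to PR-1, fell in 11 of 19 cases and rose in none: AT4G25790 was at -3.88 ± 0.317, AT1G50060 at -3.65 ± 0.64 and AT2G19970 at -3.64 ± 0.361. Camera gave adjusted p = 2.54e-05 for that family and adjusted p = 0.032 with an estimated correlation. Both camera tests kept the prompting genes, so they restate in part the pattern that led to the choice. Camera was not rerun without those genes. Without the prompting genes 6 of 14 had fallen (Fisher's exact test, adjusted p = 0.0416), and without no gold replicate 1, 10 of 19 fell. Under array median centring and quantile normalization 11 of 19 fell again, while peroxidase falls numbered 13 and 15 and rises 14 and 16.

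Berberine bridge enzyme-like oxidases rose in 8 of 22 cases and fell in 2, with AT1G26380 (7.86), AT1G26390 (5.49), AT1G26420 (4.91) and AT1G26410 (4.51) the largest rises. AT1G26400, whose locus code lies among these, was at 0.32 ± 0.15 and did not pass (limma adjusted p = 0.206). Without no gold replicate 1, 7 rose and 2 fell. The family's camera adjusted p was 0.00132, and 0.0999 with an estimated correlation. Here too camera kept the prompting genes, so these values restate in part what led to the choice. Without the prompting genes 6 of 18 had changed (Fisher's exact test, adjusted p = 0.14). Near-identical neighbours can share probe signal, and probe sequences were not analysed here. Of 15 dirigent proteins 4 rose and 2 fell (Fisher's exact test, adjusted p = 0.0361; 0.255 without the prompting genes), with AT3G13650 at 2.76 and AT4G11190 at -3.54. Probe sets without a single named gene changed in 24.0% of 9233 cases; the largest rise among those that passed was 7.78 and the largest fall -7.05 on the log2 scale.

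The array of no gold replicate 1 had low 5' signal, with a mean 5' minus 3' difference of -2.86 over 3 root control transcripts. The 4 hybridisation control transcripts, which are labelled before they are added, were at 0.02 on that array and between -0.08 and 0.13 on the others, which argues against a fault of hybridisation or scanning. A wrong group label is argued against too, since the array lay nearer to the no gold mean in 82.3% of the 4868 probe sets changed without it. Breakdown of RNA in the roots alone stays open. The 4 bacterial transcripts had a mean of -1.16 there, below the lowest of the other 5 arrays (-0.73, gold replicate 2) by less than their SD (0.56). That lowest value and the SD both depend on gold replicate 2, as the remaining arrays lay between 0.19 and 0.77. The labels do not say whether or when these transcripts were added. Short labelling products remain a further possible explanation that was not separately tested.

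Gold replicate 1 showed smaller changes than the other gold arrays. Over probe sets called without it, its median ratio to the mean change of the other gold arrays was 0.64 for 2432 rises and 0.69 for 2649 falls, against 1.21 and 1.11 for gold replicate 2 and 1.02 and 1.04 for gold replicate 3. Mixing with untreated root RNA is argued against: the rises of 4 or more would need a share of 45.3%, which limits any fall to -1.14, whereas falls of 4 or more had a median of -4.04 on this array. Whether a single scale factor held for all log2 changes on this array cannot be told. For rises, the ratio for changes of 4 or more exceeded that for changes of 1 to 2 by 0.20 (95% bootstrap interval 0.16 to 0.24). For falls the difference was 0.20 (0.13 to 0.24). Both intervals are over probe sets that are not independent. The same differences were -0.16 and -0.10 on gold replicate 2 and -0.03 and -0.02 on gold replicate 3. The ratios for gold replicates 2 and 3 use a reference that includes gold replicate 1, so part of their differences may mirror that array. They therefore give no independent measure of the spread between arrays, and none is at hand to decide the question. A jar that took up less gold, or responded less or later, may account for the smaller changes on gold replicate 1. No label or measurement here tests that hypothesis, and other processing of this array by the authors stays open.

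Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many changed probe sets as the real grouping, the real one itself. The real split gave 4601 and the highest of the other 9 gave 0 by limma (2182 at an unadjusted p under 0.05, against 7236). Each of those 9 puts gold and no gold arrays on both sides. The difference between the groups then adds to the spread and lowers the number of calls, so 0 is a weak reference. Besides, 10 splits are too few for a share under 0.05.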
